A study of Arabidopsis thaliana with 28 samples.

How the data were processed

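The samples were 28 ATH1 arrays, 1 for each of 2 replicates of shoots and roots at 7 times after the drying treatment, grouped by the tissue, time and replicate number in the labels. The deposited values are array signal intensities on a linear scale, 1 value per probe set, and MAS5 made them per the submitters' processing notes, with the version not given in the sources used here. MAS5 is the Affymetrix method that combines the probe pairs of a probe set into 1 signal and scales each array to a common mean. In the deposited table the mean signal with 2% trimmed at each end was 100.01 on each array, so total brightness is not comparable between arrays and a shift shared by most transcripts could not be seen. No detection calls were used, and signals near the lower end have no stated background.

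From the deposited signals, log2(signal + 1.93) was computed, where the pseudocount is the 10th percentile of all values, so changes of dim transcripts are understated. The 64 AFFX control probe sets were left out. A probe set was kept if it lay above its array's 30th percentile on both replicates of at least 1 group, which left 18190 probe sets and removed 4556. Array medians differed by at most 1.10 times within a tissue, under the limit of 2 set for rescaling, and no further scaling was applied. limma 3.58.1 in R 4.3.3 fitted 14 group means with a trended variance prior and 14 residual degrees of freedom, so that all arrays share the estimate of the spread. Each later time was compared with 0.25 h within each tissue, the root change with the shoot change at each time, and the mean of the root groups with that of the shoot groups. Tests were two-sided, and Benjamini-Hochberg adjustment was made within each test at 0.05. Overlaps of the 2 tissues' calls were tested with Fisher's exact test.

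Gene names came from the platform annotation given, which pairs 13513 probe sets with 1 gene, 503 with several and 8730 with none, and only probe sets with 1 gene and a symbol in the table were named. Of these, 13436 matched the TAIR10.1 gene table, used for names only, and no coordinates were used. Where the table has no symbol, the locus code stands as the name. Probe sets ending in _x_at or _s_at can share signal with other genes and are marked where named, and a gene with several probe sets was represented by the brightest. The rule for named genes took, per tissue, the 10 largest rises and 10 largest falls past both the time course F test and the contrast, with both later arrays on the same side of both reference arrays, the 3 largest each way per contrast, the 5 largest each way of the tissue difference and of root against shoot, and members of the gene lists fixed in advance. All rankings cover only the 10141 of 18190 tested probe sets with 1 gene, taking 1 probe set per gene. Larger changes of other probe sets would not appear in them. The rule, the gene lists, the design and the alternatives were fixed before the data were examined. Which list members to name, and members of the added lists and families, were chosen after their values were seen.

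Of 24 lists fixed in advance, that of ribosomal proteins, set by a rule on gene names, matched no gene and gave no result. Of 328 entries in the other lists fixed in advance, 41 had a probe set with 1 gene, so 7 lists (abscisic acid signalling and metabolism, CBF and DREB factors, ethylene, salicylate, morning clock genes and aquaporins) had no measured member and gave no result. For that reason 31 wider lists and gene families were written after the gene table was seen and before any expression difference was computed. They hold genes of late embryogenesis abundant proteins, heat shock, low oxygen, starvation, photosynthesis and the organelle genomes, and families named by shared symbols. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, with the estimated correlation beside it, and adjusted over 432 tests of 36 lists in 12 time contrasts, or over 216 tests of the tissue difference.

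The fit was tested on simulated data for shoots at 3 h, with 200 of 18190 probe sets changed by known amounts. It called 59% of the 2-fold and 93% of the 4-fold changes, made 154 calls of which 1.3% were unchanged probe sets, and made 0 calls in the unchanged roots at 3 h. The simulated noise was independent between probe sets and had the same spread on every array. The real arrays differ in spread and many more probe sets changed, so these rates need not hold for them. Alternatives changed 1 choice at a time: the pseudocount, the filter, quantile normalization, the variance prior, array weights, the replicate number as a block, the arrays in the fit, the range of the multiple testing adjustment, the reference time and each array left out in turn. A left-out array leaves its group with 1 array, which is assumed to vary like the other groups. Fits without the 4 shoot arrays of 0.5 h and 1 h, and with these 4 as 1 group, were chosen after seeing the data.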

Results

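The series follows Arabidopsis thaliana Col-0 plants over the 24 h after a short drying treatment, separately in shoots and roots. Per the labels, 16-day-old plants were placed in a stream of dry air for 15 min, 3 h into the light period, until 10% of the fresh weight was lost, and were then kept in closed vessels in a climate chamber. RNA from each tissue was hybridised to ATH1 arrays at 0.25, 0.5, 1, 3, 6, 12 and 24 h, with 2 arrays for each tissue and time, so that 14 groups of 2 arrays were compared. This series has no untreated arrays, and 0.25 h served as the reference for every later time. Time after drying and time of day move together, except that 24 h falls at nearly the clock time of 0.25 h. The labels do not say whether the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Changes are log2 changes from 0.25 h ± the standard error (SE) of limma's model, with n = 2 arrays per group, and adjusted p-values are Benjamini-Hochberg values at a threshold of 0.05.

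Each array carried signals for 22810 probe sets, and the number of arrays limits the precision. The median signal was 36.6 to 40.3 on the shoot arrays and 43.1 to 46.7 on the root arrays. Replicate arrays correlated across probe sets with r from 0.976 to 0.985 in 12 of the 14 groups. The 2 remaining groups were the shoots at 0.5 h and 1 h, where the replicates correlated at 0.953 and 0.955. Each of these 4 arrays matched an array of the other time better than its own replicate. Replicate 1 of 0.5 h and replicate 2 of 1 h correlated at 0.982, and so did replicate 2 of 0.5 h and replicate 1 of 1 h. No other array of the 28 matched an array outside its own group best.

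**Figure D1:**
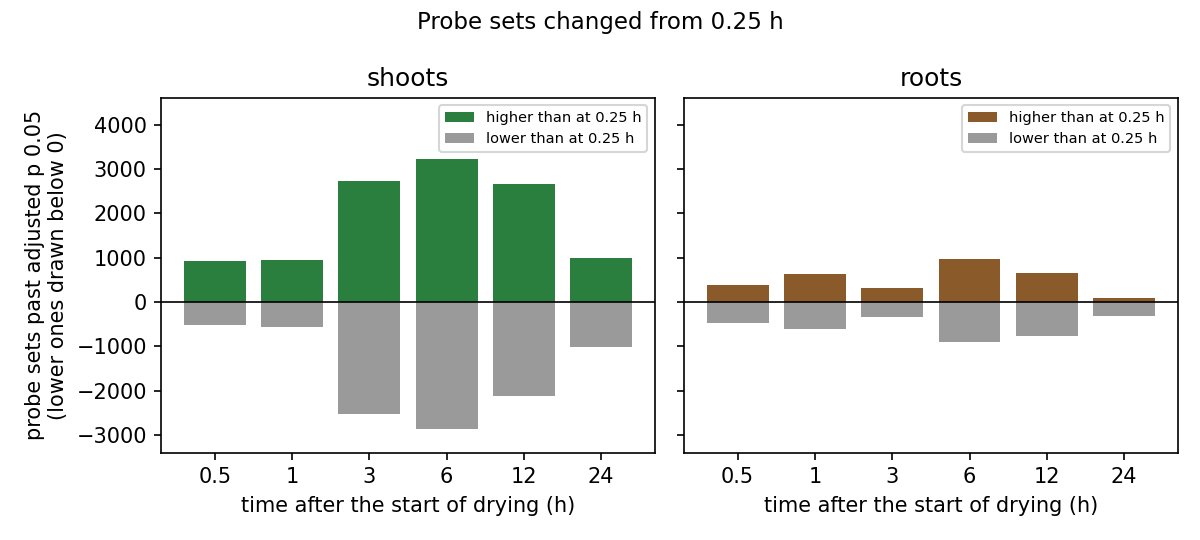
Number of probe sets past the adjusted threshold at each later time against 0.25 h, with higher ones above 0 and lower ones below 0, for shoots (left) and roots (right), 2 arrays per group. At 6 h the count was 6080 in shoots and 1880 in roots.

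Among the probe sets with 1 named gene, the 3 largest rises in shoots at 0.5 h and at 1 h were those of PUB19, AT1G20030 and AT4G33985. PUB19, a U-box ubiquitin ligase, rose by 4.1 ± 0.27 at 0.5 h and by 4.31 ± 0.27 at 1 h, from a mean signal of 32.4 to 609 and 682. The thaumatin family gene AT1G20030 rose by 4.66 ± 0.65 and 5.11 ± 0.65, and AT4G33985 by 3.46 ± 0.24 and 3.51 ± 0.24. The 2 arrays of each time lay far apart for AT1G20030, with mean signals of 115 (SD 112) and 172 (SD 180). With the 4 shoot arrays of 0.5 h and 1 h as 1 group, AT1G20030 rose by 4.89 ± 0.55. LTI30, a dehydrin, rose by 2.65 ± 0.44 and 2.82 ± 0.44. The calmodulin-like gene CML37 rose by 3.28 ± 0.72 and 3.18 ± 0.72, but with a larger pseudocount, the 30th percentile, its values were 1.59 and 1.47, not past the threshold (adjusted p = 0.0503 and 0.065). AT1G20030 had 2.76 at 0.5 h and 3.17 at 1 h, and AT4G33985 had 1.61 at 0.5 h and 1.65 at 1 h, with the larger pseudocount.

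Of the 5 measured genes of the list of dehydration and abscisic acid responsive transcripts, 1 rose at 0.5 h and 4 rose at 1 h, and none fell. Adjusted over the list alone, 5 rose at each of the 2 times. The list's median change was 1.79 at 0.5 h (adjusted p = 0.00078) and 1.95 at 1 h (adjusted p = 0.00039). With an estimated correlation both calls were lost, at an adjusted p of 0.49 for each. Of 15 measured genes of late embryogenesis abundant proteins, 4 rose at 0.5 h and 6 at 1 h, with medians of 1.16 and 0.44 (adjusted p = 0.0066 and 0.02, and 0.53 and 0.55 with an estimated correlation). These 15 include the 5 dehydration genes, so the 2 lists are not separate evidence. Of 3 measured early stress transcription factors, 2 rose at 0.5 h, also 2 adjusted over the list alone, with a median of 1.98 (adjusted p = 0.019, and 0.53 with an estimated correlation). These were WRKY53 at 1.98 ± 0.34 and WRKY6 at 2.43 ± 0.53, both WRKY factors linked to senescence, while the zinc finger repressor STZ had a change of 0.09 ± 0.35 (adjusted p = 0.91), and 2.44 with the mean of 0.25 h and 24 h as reference (adjusted p = 4.2e-05). At 1 h 2 of the 3 rose, also 2 adjusted over the list alone, with a median of 1.81, and the set test gave an adjusted p of 0.053. Of 8 measured U-box proteins, 2 rose at 0.5 h and 2 at 1 h, with medians of 0.54 and 0.46 (adjusted p = 6.6e-06 and 1.7e-05, and 0.19 and 0.2 with an estimated correlation). These were PUB19 and PUB24, the latter at 1.68 ± 0.16 at 0.5 h. BZIP60, a factor of the unfolded protein response, rose by 1.98 ± 0.14 at 0.5 h. The largest falls of named genes at 0.5 h were those of AT5G20790 (-2.53 ± 0.49), AT2G27610 (-2.11 ± 0.47) and AT1G78450 (-2.11 ± 0.53). At 1 h they were AT1G14220 (-2.05 ± 0.41), AT2G47560 (-1.92 ± 0.55) and AT2G38690 (-1.80 ± 0.30). The dehydration genes at 0.5 h were not past the set test without shoot 0.5 h replicate 2 (median 1.11, adjusted p = 0.081). The dehydration genes at 1 h were not past the set test without shoot 1 h replicate 1 (median 1.07, adjusted p = 0.058). The early stress factors at 0.5 h were not past the set test without shoot 0.25 h replicate 1 (median 1.83, adjusted p = 0.1) or shoot 0.5 h replicate 2 (median 1.46, adjusted p = 0.15). The late embryogenesis abundant genes at 0.5 h were not past the set test without shoot 0.5 h replicate 2 (median 0.57, adjusted p = 0.14). The late embryogenesis abundant genes at 1 h were not past the set test without shoot 0.25 h replicate 1 (median 0.83, adjusted p = 0.075) or shoot 1 h replicate 1 (median 0.28, adjusted p = 0.52). WRKY6 had 1.45 at 0.5 h, AT5G20790 had -1.13 at 0.5 h, AT2G27610 had -0.74 at 0.5 h, AT1G78450 had -1.20 at 0.5 h, and AT1G14220 had -0.83 at 1 h, with the larger pseudocount. AT2G47560 had -1.06 at 1 h, and AT2G38690 had -0.66 at 1 h, with the larger pseudocount. AT5G20790 had -1.69 at 0.5 h, and AT2G27610 had -1.32 at 0.5 h, against the mean of 0.25 h and 24 h. AT2G27610 had -3.37 at 0.5 h, and AT2G38690 had -2.75 at 1 h, with no pseudocount. AT2G38690 had -1.17 at 1 h, with the 4 doubtful shoot arrays as 1 group. Of the medians still past the set test, that of the dehydration genes at 0.5 h was 2.77 without shoot 0.5 h replicate 1, that of the dehydration genes at 1 h was 3.17 without shoot 1 h replicate 2, that of the U-box proteins at 0.5 h was 0.84 without shoot 0.5 h replicate 1 and 0.27 without shoot 0.5 h replicate 2, and that of the U-box proteins at 1 h was 0.16 without shoot 1 h replicate 1.

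In all, 1444 of 18190 tested probe sets changed at 0.5 h, 925 up and 519 down, and 1510 changed at 1 h, 940 up and 570 down. These counts rest on the 4 shoot arrays that match across their labels: with all 4 as 1 group, an alternative chosen after seeing the data, 2515 probe sets changed, and in that fit PUB19 rose by 4.2 ± 0.23 and LTI30 by 2.74 ± 0.37. With 1 array left out the counts ranged from 599 to 2360 at 0.5 h and from 362 to 2452 at 1 h, and CML37, WRKY6, AT2G27610, AT1G78450 and AT2G47560 were not past the threshold when only the 14 shoot arrays were fitted (adjusted p = 0.055 and 0.06, 0.075, 0.053, 0.056 and 0.14). CML37 at 0.5 h was not past the threshold without shoot 0.25 h replicate 1 (adjusted p = 0.054) or shoot 0.25 h replicate 2 (adjusted p = 0.055) or shoot 0.5 h replicate 2 (log2 change 1.92, adjusted p = 0.16). CML37 at 1 h was not past the threshold without shoot 0.25 h replicate 1 (adjusted p = 0.06) or shoot 0.25 h replicate 2 (adjusted p = 0.061) or shoot 1 h replicate 1 (log2 change 2.09, adjusted p = 0.2). WRKY6 at 0.5 h was not past the threshold without shoot 0.25 h replicate 1 (adjusted p = 0.11) or shoot 0.5 h replicate 2 (log2 change 1.45, adjusted p = 0.14). AT2G27610 at 0.5 h was not past the threshold without shoot 0.25 h replicate 1 (adjusted p = 0.057) or shoot 0.25 h replicate 2 (adjusted p = 0.055) or shoot 0.5 h replicate 2 (adjusted p = 0.061). AT1G78450 at 0.5 h was not past the threshold without shoot 0.25 h replicate 1 (adjusted p = 0.078) or shoot 0.25 h replicate 2 (adjusted p = 0.12) or shoot 0.5 h replicate 2 (log2 change -1.15, adjusted p = 0.28). AT2G47560 at 1 h was not past the threshold without shoot 0.25 h replicate 1 (adjusted p = 0.13) or shoot 0.25 h replicate 2 (adjusted p = 0.15) or shoot 1 h replicate 1 (adjusted p = 0.36). AT1G14220 at 1 h was not past the threshold without shoot 0.25 h replicate 2 (adjusted p = 0.051).

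More probe sets changed in shoots from 3 h to 12 h than at 0.5 h and 1 h. COR15A, which encodes a chloroplast protein that protects membranes during freezing, rose by 6.0 ± 0.77 at 3 h, from a mean signal of 33.9 to 2272, and was still higher at 6 h by 4.58 ± 0.77. AT4G17470 rose by 7.94 ± 0.45 at 3 h, 7.71 ± 0.45 at 6 h and 6.52 ± 0.45 at 12 h, from a signal of 2.16 to 1004 at 3 h. AT5G62360, a pectin methylesterase inhibitor family gene, rose by 6.81 ± 0.62 at 6 h. COR27, a cold regulated gene of the circadian clock, rose by 6.05 ± 0.35 at 6 h and 5.25 ± 0.35 at 12 h, and AT4G33980, its relative COR28, by 5.47 ± 0.47 at 6 h. Over the same hours the zinc finger repressor STZ fell, with a change of -4.45 ± 0.35 at 3 h. AT4G17470 had 5.07 at 3 h, 4.84 at 6 h and 3.66 at 12 h, and STZ had -2.11 at 3 h, against the mean of 0.25 h and 24 h. COR27 had 3.62 at 6 h and 2.89 at 12 h, and AT4G33980 had 3.59 at 6 h, with the larger pseudocount.

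Of the 5 dehydration genes, 3 rose at 3 h, 4 at 6 h and 2 at 12 h, the same counts as when adjusted over the list alone. The median was 2.83 at 3 h (adjusted p = 0.01, and 0.55 with an estimated correlation) and 2.36 at 6 h, where the set test gave an adjusted p of 0.088. Besides COR15A they included its neighbour COR15B at 4.31 ± 0.59 at 3 h and 4.63 ± 0.59 at 6 h, and LTI30 at 2.83 ± 0.44 at 3 h. Other large rises at 6 h were those of AT1G20030 (5.86 ± 0.65), AT4G30650, a low temperature and salt responsive gene (5.51 ± 0.49), and AT1G56300, a DnaJ domain chaperone (5.27 ± 0.26). At 12 h AT2G23910 rose by 5.18 ± 0.44 and AT4G34950 by 4.99 ± 0.35. GI, the only measured member of the evening clock list, rose by 3.47 ± 0.27 at 6 h, also when adjusted over the list alone. Of 7 measured genes of dark and sugar starvation, branched-chain amino acid breakdown included, 4 rose at 3 h and 4 at 6 h, with medians of 1.09 and 1.32 (adjusted p = 0.02 and 0.01, and 0.55 and 0.53 with an estimated correlation). They included IVD, isovaleryl-CoA dehydrogenase, at 1.62 ± 0.21 at 3 h, and MCCA, a subunit of methylcrotonyl-CoA carboxylase, at 1.97 ± 0.21 at 6 h. Without the 4 doubtful shoot arrays the set test of the starvation genes at 3 h gave an adjusted p of 0.0504. Of 14 beta-glucosidases, 6 rose and 2 fell at 3 h, with a median of 0.80 (adjusted p = 0.022, and 0.45 with an estimated correlation), and BGLU44 rose by 3.58 ± 0.19 at 6 h. Of 38 UDP-glycosyltransferases, 13 rose and 2 fell at 12 h, with a median of 0.51 (adjusted p = 0.048, and 0.19 with an estimated correlation). Of 27 low-oxygen genes, 6 rose and 5 fell at 6 h, with a median of 0.06 and an adjusted p of 0.98 in the set test. PDF1.2, a defensin induced by jasmonate and ethylene, rose by 3.85 ± 0.48 at 12 h, and PDC2, a pyruvate decarboxylase, by 3.37 ± 0.39 at 6 h. The starvation genes at 3 h were not past the set test without shoot 0.25 h replicate 1 (median 0.95, adjusted p = 0.094) or shoot 3 h replicate 2 (median 0.75, adjusted p = 0.074). The beta-glucosidases at 3 h were not past the set test without shoot 0.25 h replicate 2 (median 0.53, adjusted p = 0.1) or shoot 3 h replicate 1 (median 0.76, adjusted p = 0.052). The UDP-glycosyltransferases at 12 h were not past it in 11 fits with 1 array left out (adjusted p from 0.05 to 0.075). AT1G20030 had 3.81 at 6 h, and AT2G23910 had 2.85 at 12 h, with the larger pseudocount.

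Of the 10 largest falls of named genes in shoots, 9 were at 3 h to 12 h, and that of STZ was at 24 h. The cysteine protease family gene AT2G27420 fell, with a change of -5.22 ± 0.32 at 6 h, from a signal of 391 to 8.5. At 12 h AT5G62280 changed by -5.47 ± 0.78, AT2G20670 by -4.87 ± 1.07, the lipid transfer family gene AT1G62510 by -4.37 ± 0.29 and the glutaredoxin AT3G62950 by -4.17 ± 0.58. AT4G27657, AT2G15020 and AT3G10930 changed by -4.30 ± 0.58, -3.84 ± 0.36 and -3.83 ± 0.42 at 6 h. AT4G11710 changed by -4.90 ± 1.09 at 3 h, from a probe set that can share signal with other genes. Of the 3 early stress factors, 2 fell at 3 h, also 2 adjusted over the list alone, with a median of -1.92 (adjusted p = 0.02, and 0.57 with an estimated correlation). They were STZ and WRKY53, the latter at -1.92 ± 0.34. ARR15, a type A response regulator induced by cytokinin, fell, with -2.72 ± 0.51 at 6 h, and so did XTH19, a xyloglucan endotransglucosylase, with -3.73 ± 0.77. At 3 h 5246 probe sets changed (2718 up, 2528 down), at 6 h 6080 (3214 up, 2866 down) and at 12 h 4793 (2666 up, 2127 down). With 1 array left out these counts ranged from 3375 to 3905, 4403 to 4751 and 3185 to 3552. The larger side turned with quantile normalization at 3 h (2470 up, 2534 down), against the mean of 0.25 h and 24 h at 3 h (2344 up, 2423 down), with quantile normalization at 6 h (2867 up, 2939 down) and without shoot 6 h replicate 1 at 6 h (2331 up, 2382 down). The early stress factors at 3 h were not past the set test without shoot 0.25 h replicate 2 (median -1.89, adjusted p = 0.087). AT5G62280 had -3.32 at 12 h, AT3G62950 had -2.36 at 12 h, AT4G27657 had -2.42 at 6 h, AT3G10930 had -2.07 at 6 h, and AT4G11710 had -2.60 at 3 h, with the larger pseudocount. WRKY53 had -1.21 at 3 h, ARR15 had -1.61 at 6 h, and XTH19 had -1.67 at 6 h, with the larger pseudocount. AT3G10930 had -1.92 at 6 h, AT4G11710 had -2.57 at 3 h (adjusted p = 0.052), and WRKY53 had -1.17 at 3 h, against the mean of 0.25 h and 24 h. ARR15 had -1.64 at 6 h, without shoot 6 h replicate 2.

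At 24 h, near the clock time of the reference, part of the shoot changes remained measurable. AT4G17470 was higher by 5.73 ± 0.45, JRG21, a jasmonate regulated oxygenase, by 3.49 ± 0.54, and AT1G76960 by 3.49 ± 0.72. STZ was lower, with a change of -4.69 ± 0.35 and a signal of 14.1 against 409, as were AT4G11710 (-4.66 ± 1.09) and AT3G10930 (-3.81 ± 0.42). Of the 3 early stress factors, 2 fell, also 2 adjusted over the list alone, with a median of -1.49 (adjusted p = 2.0e-05, and 0.42 with an estimated correlation). None of the 5 dehydration genes passed the test at 24 h in limma, over all genes or adjusted over the list alone, and their median was 0.50. In all 2005 probe sets changed, 980 up and 1025 down, and without shoot 24 h replicate 1 the split was 591 up and 966 down. The larger side turned with only the 14 arrays of shoots (673 up, 654 down), without shoot 0.25 h replicate 1 (501 up, 447 down) and without the 4 doubtful shoot arrays (1435 up, 1302 down). With 1 array left out the count ranged from 654 to 1557, and 1327 probe sets changed when only the 14 shoot arrays were fitted, where AT4G11710 had an adjusted p of 0.067. AT4G11710 at 24 h was not past the threshold without shoot 0.25 h replicate 1 (adjusted p = 0.058) or shoot 0.25 h replicate 2 (adjusted p = 0.055) or shoot 24 h replicate 2 (adjusted p = 0.082). AT1G76960 at 24 h was not past the threshold without shoot 24 h replicate 2 (adjusted p = 0.092). JRG21 had 2.14 at 24 h, AT1G76960 had 1.58 at 24 h, AT4G11710 had -2.55 at 24 h, and AT3G10930 had -2.06 at 24 h, with the larger pseudocount.

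**Figure D2:**
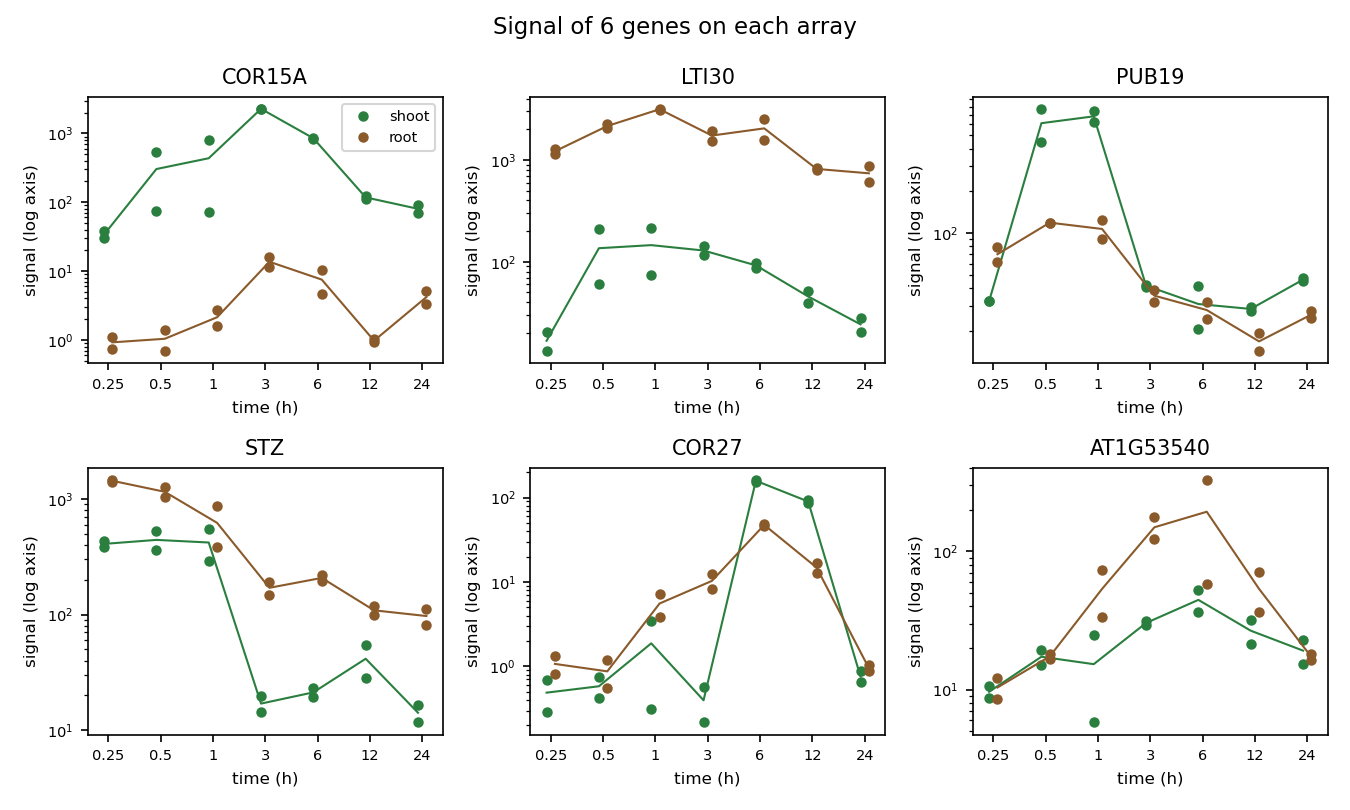
Signal of 6 genes on each array (points, log axis) against time, shoots in green and roots in brown, 2 arrays per group, with lines through the group means. COR15A peaks in shoots at 3 h at a mean of 2272, and STZ falls in shoots from 409 at 0.25 h to 17 at 3 h.

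In roots at 0.5 h and 1 h, the aspartyl protease family gene AT5G19110 rose by 4.35 ± 0.64 at 0.5 h and 4.28 ± 0.64 at 1 h, from a signal of 20.4 to 457 at 0.5 h. AT3G28600 rose by 4.32 ± 0.66 at 1 h and AT5G62360 by 3.76 ± 0.62, while the leucine-rich repeat gene AT2G34930 and the subtilase AT1G32970 rose by 3.69 ± 0.83 and 3.5 ± 0.65 at 0.5 h. ICL, isocitrate lyase of the glyoxylate cycle, fell, with a change of -2.74 ± 0.55 at 0.5 h. AT3G01490 changed by -2.87 ± 0.64 at 0.5 h, and AT4G27657 by -2.82 ± 0.58 at 1 h. AT3G28600 had 2.68 at 1 h, AT5G62360 had 2.43 at 1 h, and AT3G01490 had -1.29 at 0.5 h, with the larger pseudocount. AT4G27657 had -0.35 at 1 h (adjusted p = 0.73), against the mean of 0.25 h and 24 h.

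Of 69 genes of the plastid genome, 11 rose at 0.5 h and 30 at 1 h, and none fell. The list's median was 0.34 at 0.5 h and 0.64 at 1 h (adjusted p = 2.6e-11 and 4.6e-27, and 0.53 and 0.25 with an estimated correlation). On the single arrays of 1 h the median was 0.72 and 0.49, while that of 12 nuclear photosynthesis genes, markers of green tissue, was 0.65 and -0.72. Of 14 genes of the mitochondrial genome, 2 rose at 0.5 h and 4 at 1 h, with medians of 0.32 and 0.52 (adjusted p = 0.00081 for each, and 0.55 with an estimated correlation). Of 27 low-oxygen response genes, 5 fell at 0.5 h and 6 at 1 h, with medians of -0.97 and -0.54 (adjusted p = 1.7e-05 and 0.0086, and 0.55 and 0.73 with an estimated correlation). They included AT3G29970 at -2.72 ± 0.65 and -3.08 ± 0.65, and AT2G17850 at -2.81 ± 0.65 at 1 h. Of 14 beta-glucosidases, 3 rose at 0.5 h and 4 at 1 h, with medians of 0.23 and 0.31 (adjusted p = 0.0029 and 0.0023, and 0.25 for each with an estimated correlation). Of the 2 measured osmolyte genes, AT5G38710, a proline dehydrogenase, rose by 2.57 ± 0.26 at 0.5 h, the only one of the 2 also when adjusted over the list alone. SWEET16, a vacuolar sugar transporter, rose by 2.03 ± 0.29 at 0.5 h. In all 875 probe sets changed at 0.5 h (388 up, 487 down) and 1244 at 1 h (633 up, 611 down), and without the 4 doubtful shoot arrays, which share the estimate of the spread, 1470 and 1940. Left out singly, arrays moved the counts to 135 to 535 and 322 to 867, and at 0.5 h the larger side turned without root 0.25 h replicate 1 (105 up, 86 down) or replicate 2 (285 up, 250 down) or root 0.5 h replicate 2 (76 up, 59 down). ICL at 0.5 h was not past the threshold without root 0.25 h replicate 1 (log2 change -1.72, adjusted p = 0.17) or root 0.5 h replicate 1 (adjusted p = 0.09). AT3G01490 at 0.5 h was not past the threshold without root 0.25 h replicate 1 (log2 change -1.85, adjusted p = 0.24) or root 0.5 h replicate 1 (adjusted p = 0.081) or root 0.5 h replicate 2 (adjusted p = 0.11). AT2G34930 at 0.5 h was not past the threshold without root 0.25 h replicate 1 (adjusted p = 0.12) or root 0.25 h replicate 2 (adjusted p = 0.064) or root 0.5 h replicate 1 (adjusted p = 0.063) or root 0.5 h replicate 2 (adjusted p = 0.14). AT1G32970 at 0.5 h was not past the threshold without root 0.25 h replicate 1 (adjusted p = 0.056) or root 0.5 h replicate 2 (adjusted p = 0.069). AT3G29970 at 0.5 h was not past the threshold without root 0.25 h replicate 1 (adjusted p = 0.14) or root 0.25 h replicate 2 (adjusted p = 0.082) or root 0.5 h replicate 1 (adjusted p = 0.13) or root 0.5 h replicate 2 (adjusted p = 0.1). AT3G29970 at 1 h was not past the threshold without root 0.25 h replicate 1 (adjusted p = 0.067) or root 1 h replicate 2 (adjusted p = 0.096). AT2G17850 at 1 h was not past the threshold without root 0.25 h replicate 1 (adjusted p = 0.12) or root 1 h replicate 2 (adjusted p = 0.11). AT4G27657 at 1 h was not past the threshold without root 0.25 h replicate 2 (adjusted p = 0.055) or root 1 h replicate 1 (adjusted p = 0.066). At 1 h the larger side turned with no pseudocount (573 up, 580 down), with the filter at the array median (649 up, 661 down), with quantile normalization (746 up, 751 down), with array weights (923 up, 952 down), with adjustment over all 12 contrasts (789 up, 811 down) and against the mean of 0.25 h and 24 h (1034 up, 1098 down). AT3G29970 had -1.46 at 0.5 h (adjusted p = 0.12) and -1.82 at 1 h, against the mean of 0.25 h and 24 h. Of the medians still past the set test, that of the plastid genes at 0.5 h was 0.19 without root 0.5 h replicate 1 and 0.53 without root 0.5 h replicate 2, that of the beta-glucosidases at 0.5 h was 0.09 without root 0.25 h replicate 1 and 0.40 without root 0.25 h replicate 2, and that of the beta-glucosidases at 1 h was 0.50 without root 0.25 h replicate 2.

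In roots AT1G53540 and AT2G29500, both small heat shock proteins, rose by 3.61 ± 0.60 and 3.19 ± 0.62 at 3 h, and AT1G11210 by 3.07 ± 0.30. At 6 h JRG21 rose by 4.13 ± 0.54, COR27 by 4.04 ± 0.35, the defensin PDF2.1 by 4.0 ± 0.65, AT2G15780 by 3.90 ± 0.94 and AT1G11210 by 3.71 ± 0.30. At 12 h AT2G16005 rose by 3.81 ± 0.41, AT2G23910 by 3.52 ± 0.44 and AT4G11190 by 3.43 ± 0.75. At 3 h AT4G27654, AT4G27652 and AT4G27657 fell, with changes of -4.49, -3.91 and -3.76. Against the mean of 0.25 h and 24 h these values were -2.05, -1.68 and -1.28. With that reference AT4G27657 was not past the threshold in limma (adjusted p = 0.16). AT4G29780 fell, with a change of -4.35 ± 0.30 at 6 h and -4.84 ± 0.30 at 12 h, and AT4G27652 and AT4G27654 changed by -4.74 ± 0.34 and -4.54 ± 0.41 at 12 h. AT1G73120 changed by -4.52 ± 0.49 and AT5G58680 by -4.21 ± 0.76 at 6 h, and AT5G52760 and the calmodulin-like gene AT1G76640 by -4.38 ± 0.92 and -4.11 ± 0.82 at 12 h. With the mean of 0.25 h and 24 h as reference AT1G76640 at 12 h had -2.43, not past the threshold (adjusted p = 0.051). AT1G11210 had 1.78 at 3 h and 2.32 at 6 h, JRG21 had 2.20 at 6 h, COR27 had 2.07 at 6 h, AT1G73120 had -2.79 at 6 h, and AT5G58680 had -2.12 at 6 h, with the larger pseudocount. AT1G76640 had -2.12 at 12 h, with the larger pseudocount. JRG21 had 2.67 at 6 h, AT2G16005 had 2.24 at 12 h, AT4G29780 had -2.03 at 6 h and -2.52 at 12 h, AT4G27652 had -2.50 at 12 h, and AT4G27654 had -2.09 at 12 h, against the mean of 0.25 h and 24 h. AT5G58680 had -2.42 at 6 h, against the mean of 0.25 h and 24 h.

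Of 13 measured heat shock genes, 2 rose at 1 h, 7 at 3 h and 4 at 6 h, and none fell. Their medians were 0.57, 1.27 and 0.56 (adjusted p = 0.00093, 9.1e-08 and 0.0041, and 0.49, 0.25 and 0.53 with an estimated correlation). In the shorter heat shock list, 1 of the 2 measured genes rose at 3 h, and both when adjusted over the list alone. Of the 3 early stress factors, 2 fell at each of 3, 6 and 12 h, over all genes and adjusted over the list alone. Their medians were -2.13, -2.05 and -2.21 (adjusted p = 2.2e-05, 0.0045 and 1.9e-05, and 0.29, 0.53 and 0.27 with an estimated correlation). STZ was among them, at -3.07 ± 0.35 at 3 h. Of the 7 starvation genes, 1 rose at 3 h and 5 at 6 h, with medians of 0.76 and 1.11 (adjusted p = 0.021 and 2.0e-05, and 0.55 and 0.27 with an estimated correlation). Of the 27 low-oxygen genes, 9 fell at 6 h and 4 at 12 h, with medians of -0.71 and -0.47 (adjusted p = 0.00034 and 0.006, and 0.57 and 0.7 with an estimated correlation). At 3 h 1 of the 27 rose and 1 fell, with a median of 0.31 and an adjusted p of 0.16 in the set test. Of the 69 plastid genes, 9 rose at 3 h and 16 at 6 h (medians 0.44 and 0.42, adjusted p = 6.0e-12 and 3.0e-08, and 0.53 and 0.55 with an estimated correlation). Of the 14 mitochondrial genes 2 rose at 3 h, and of the 14 beta-glucosidases 2 (medians 0.39 and 0.29, adjusted p = 0.0029 and 0.0023, and 0.55 and 0.25 with an estimated correlation). Of the 8 U-box proteins, 1 fell at 3 h, 4 at 6 h and 5 at 12 h (medians -0.48, -0.80 and -0.84, adjusted p = 0.0024, 0.004 and 5.1e-05, and 0.19, 0.19 and 0.097 with an estimated correlation), and PUB19 changed by -1.95 ± 0.27 at 12 h. None of the 5 dehydration genes passed the test in roots at any time in limma, with medians from -0.49 to 0.76, and adjusted over the list alone 2 rose at 1 h and 1 at 3 h. LTI30 had root signals of 1292 and 1143 at 0.25 h and 3106 and 3192 at 1 h. COR15A had 0.73 and 1.11 at 0.25 h, under the pseudocount, and 11.3 and 15.9 at 3 h. The lack of a call therefore does not show the lack of a change. The counts were 651 at 3 h (319 up, 332 down), 1880 at 6 h (968 up, 912 down) and 1434 at 12 h (659 up, 775 down), and without the 4 doubtful shoot arrays 995 at 3 h. With 1 array left out they ranged from 213 to 596, 802 to 1370 and 561 to 994, and the larger side turned without root 0.25 h replicate 2 at 3 h (319 up, 277 down), without the 4 doubtful shoot arrays at 3 h (515 up, 480 down), against the mean of 0.25 h and 24 h at 6 h (1052 up, 1168 down), without root 0.25 h replicate 1 at 6 h (391 up, 411 down) and without root 6 h replicate 2 at 6 h (432 up, 479 down). The heat shock genes at 6 h were not past the set test without root 6 h replicate 2 (median 0.33, adjusted p = 0.33). The low-oxygen genes at 6 h were not past the set test without root 6 h replicate 1 (median -0.26, adjusted p = 0.27). The low-oxygen genes at 12 h were not past the set test without root 12 h replicate 2 (median -0.29, adjusted p = 0.073). The starvation genes at 3 h were not past the set test without root 0.25 h replicate 2 (median 0.72, adjusted p = 0.084) or root 3 h replicate 2 (median 0.55, adjusted p = 0.44). AT2G29500 at 3 h was not past the threshold without root 0.25 h replicate 1 (adjusted p = 0.069) or root 3 h replicate 2 (adjusted p = 0.094). AT2G15780 at 6 h was not past the threshold without root 0.25 h replicate 1 (adjusted p = 0.088) or root 6 h replicate 2 (adjusted p = 0.16). AT4G11190 at 12 h was not past the threshold without root 0.25 h replicate 1 (log2 change 2.14, adjusted p = 0.17) or root 12 h replicate 2 (adjusted p = 0.077). AT5G52760 at 12 h was not past the threshold without root 0.25 h replicate 1 (adjusted p = 0.052) or root 12 h replicate 2 (adjusted p = 0.11). STZ had -1.13 at 3 h, and PUB19 had -1.27 at 12 h, against the mean of 0.25 h and 24 h. Of the medians still past the set test, that of the heat shock genes at 6 h was 1.06 without root 6 h replicate 1, that of the low-oxygen genes at 6 h was -1.23 without root 6 h replicate 2, that of the plastid genes at 3 h was 0.29 without root 0.25 h replicate 1, and that of the beta-glucosidases at 3 h was 0.46 without root 3 h replicate 1.

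At 24 h most of the changed probe sets in roots were lower than at 0.25 h. AT4G27657, AT4G27654 and AT4G29780 fell, with changes of -4.95 ± 0.58, -4.88 ± 0.41 and -4.64 ± 0.30. CML37 fell from a signal of 145 to 6.28, a change of -4.17 ± 0.72, and AT3G01830 changed by -4.02 ± 0.85. AT2G16005 was higher by 3.14 ± 0.41, JRG21 by 2.93 ± 0.54 and AT5G37990 by 2.41 ± 0.51. Of the 3 early stress factors, 2 fell, also 2 adjusted over the list alone, with a median of -2.41 (adjusted p = 7.7e-10, and 0.19 with an estimated correlation). They were STZ at -3.88 ± 0.35 and WRKY53 at -2.41 ± 0.34. Of the 8 U-box proteins, 3 fell, with a median of -0.62 (adjusted p = 6.1e-07, and 0.03 with an estimated correlation), the only list call of the time contrasts that held with an estimated correlation; PUB23 changed by -2.03 ± 0.27. Of 7 calmodulin-like genes 3 fell and of 5 WRKY factors 1, with medians of -0.20 and -0.38 (adjusted p = 0.0053 and 0.011, and 0.2 and 0.25 with an estimated correlation). The 5 WRKY factors include WRKY53 and WRKY6 of the early stress factors, so these 2 lists overlap. Of the 27 low-oxygen genes 4 fell and of the 69 plastid genes 2, with medians of -0.63 and -0.25 (adjusted p = 3.0e-08 and 1.5e-05, and 0.45 and 0.63 with an estimated correlation). In all 402 probe sets changed, 91 up and 311 down, and without the 4 doubtful shoot arrays 653. Left out singly, arrays moved the count to 211 to 341. AT3G01830 at 24 h was not past the threshold without root 0.25 h replicate 1 (adjusted p = 0.1) or root 0.25 h replicate 2 (adjusted p = 0.063) or root 24 h replicate 1 (adjusted p = 0.072) or root 24 h replicate 2 (adjusted p = 0.1). JRG21 at 24 h was not past the threshold without root 0.25 h replicate 1 (adjusted p = 0.054) or root 24 h replicate 1 (adjusted p = 0.12), and with the larger pseudocount it had 1.31 (adjusted p = 0.063). AT5G37990 at 24 h was not past the threshold without root 0.25 h replicate 1 (adjusted p = 0.24) or root 24 h replicate 1 (adjusted p = 0.16). The WRKY factors at 24 h were not past the set test without root 24 h replicate 2 (median -0.10, adjusted p = 0.13). AT4G27657 had -2.98 at 24 h, and AT3G01830 had -2.66 at 24 h, with the larger pseudocount. Of the medians still past the set test, that of the calmodulin-like genes at 24 h was -0.11 without root 0.25 h replicate 2, -0.09 without root 24 h replicate 1 and -0.32 without root 24 h replicate 2, that of the WRKY factors at 24 h was -0.65 without root 24 h replicate 1, and that of the plastid genes at 24 h was -0.13 without root 0.25 h replicate 2.

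**Figure D3:**
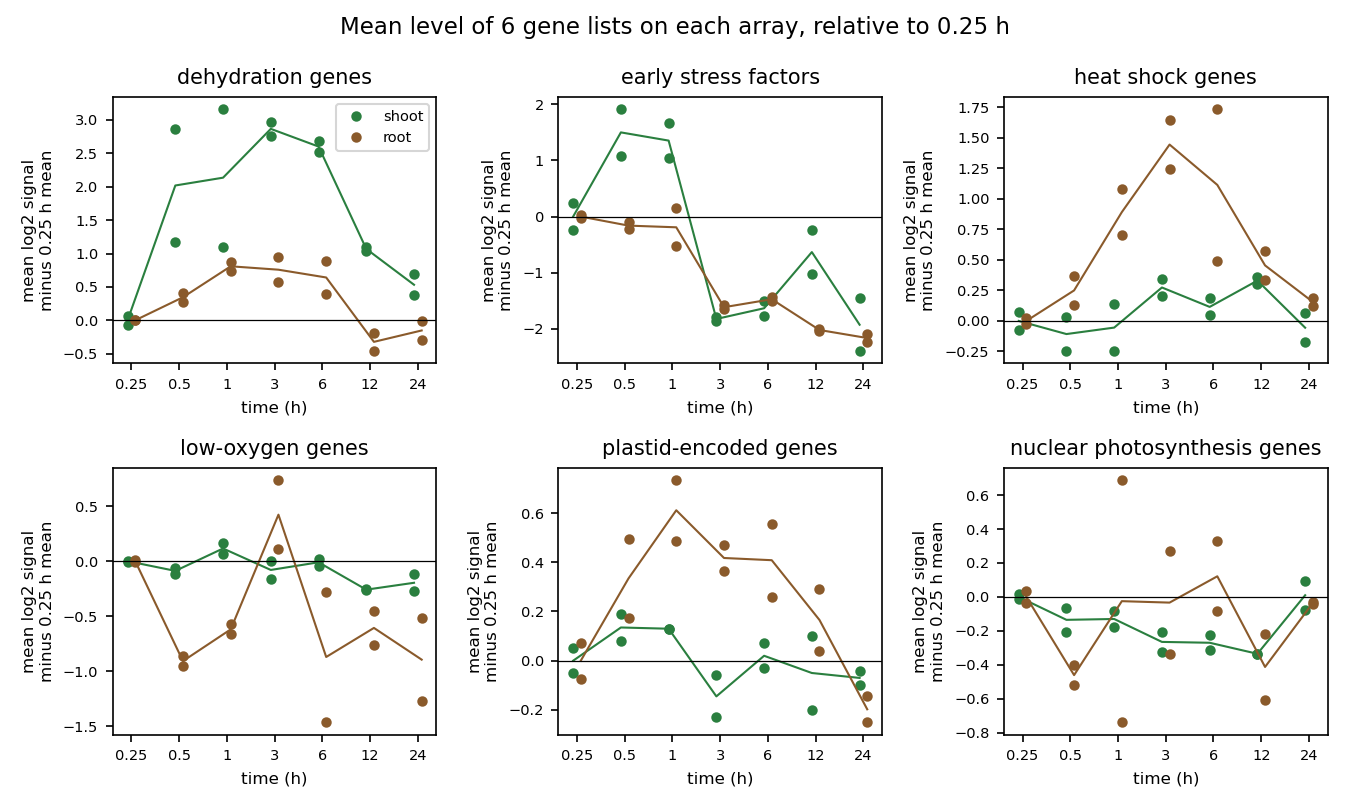
Mean log2 signal of 6 gene lists on each array minus the mean of the 2 arrays of 0.25 h of that tissue, against time, shoots in green and roots in brown, with lines through the group means. At 3 h the median change of the dehydration genes in shoots was 2.83, with 3 of 5 past the test. That of the heat shock genes in roots was 1.27, with 7 of 13 past it. Both list calls were lost with an estimated correlation.

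The time courses differed between the tissues in the test of the difference itself. AT4G17470 rose in shoots at 3 h, and its root change minus its shoot change was -8.07 ± 0.63. AT3G60420 and AT1G19960 had differences of -5.96 ± 1.01 and -5.56 ± 0.63 at 12 h, and AT1G07050 and AT3G62550 of -5.27 ± 0.64 and -5.19 ± 0.57 at 6 h. In the other direction AT2G27420 had a difference of 5.43 ± 0.46 and AT5G52390 of 4.12 ± 0.91 at 6 h, and AT5G62280 and AT3G62950 of 4.58 ± 1.11 and 4.14 ± 0.82 at 12 h. SWEET2, a vacuolar sugar transporter, fell in shoots at 6 h by 3.38, and its difference was 4.19 ± 0.45. Of 18190 probe sets, 385 differed at 0.5 h, 542 at 1 h, 1978 at 3 h, 3067 at 6 h, 2875 at 12 h and 587 at 24 h. Over all times together, 9160 changed in shoots, 5018 in roots, and 5214 differed between the tissues in the F test. The counts of the difference with 1 array left out ranged from 137 to 746 at 0.5 h, 261 to 988 at 1 h, 1107 to 1583 at 3 h, 2004 to 2846 at 6 h, 1927 to 2311 at 12 h and 159 to 715 at 24 h. AT3G60420 had -3.50 at 12 h, AT5G62280 had 2.55 at 12 h, and AT3G62950 had 2.36 at 12 h, with the larger pseudocount.

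Calls in shoots and roots also shared direction more often than independent lists would. The 2 tissues share no arrays, but all arrays share the estimate of the spread, so the calls of the 2 tissues are not independent. At 3 h 171 probe sets rose and 197 fell in both tissues, against 47.7 and 46.1 in independent lists. At 6 h 483 rose and 452 fell in both, against 171 and 144, and among those that rose was COR27. At 24 h 22 rose and 114 fell in both, against 4.9 and 17.5, with STZ among those that fell. At 0.5, 1 and 12 h 91, 88 and 239 rose in both and 37, 63 and 277 fell in both. Fisher's exact test, which takes probe sets as independent although they are not, gave an adjusted p of at most 6.7e-08 for each direction and time. Opposite calls were fewer than in independent lists at each time. At 3 h 11 probe sets rose in shoots and fell in roots, against 49.6, and 7 did the reverse, against 44.3. Across probe sets, which are not independent replicates, Pearson's r of the changes was 0.27, 0.24, 0.36, 0.37, 0.28 and 0.29 from 0.5 h to 24 h, and Spearman's rho was 0.23, 0.24, 0.30, 0.32, 0.16 and 0.13.

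Between the tissues, averaged over all times, the named genes had mean signals of 0.69 to 19.9 in the dimmer tissue, so that the size of each difference depends on the pseudocount. Higher in roots were AT4G15390 (8.25 ± 0.12), AT5G66985 (7.73 ± 0.12), the peroxidase AT4G30170 (7.52 ± 0.17), AT1G19530 (7.51 ± 0.14) and AT4G39675 (7.50 ± 0.19), each with n = 14 arrays per tissue, and with the larger pseudocount these values were 6.24, 5.32, 6.02, 5.41 and 5.82. Higher in shoots were AT1G23130 (-9.16 ± 0.10), AT2G10940 (-8.70 ± 0.22), ECS1 (-8.07 ± 0.14), AT1G09310 (-8.01 ± 0.14) and AT3G28220 (-7.71 ± 0.09), and with the larger pseudocount these values were -7.26, -6.77, -7.38, -6.81 and -5.72. All 6 measured genes of the fixed photosynthesis list, all 12 of the wider photosynthesis list and all 69 plastid genes were higher in shoots, with medians of -5.91, -5.94 and -2.82. All 3 measured root markers were higher in roots, with a median of 1.81, and so were 22 of 27 low-oxygen genes, with a median of 2.78. Of 4 reference genes 3 were higher in roots, with a median of 0.37. In all 15827 probe sets differed, 10084 higher and 5743 lower in roots, and quantile normalization moved the median over all probe sets from 0.29 to 0.16, so these values lie on a background of that size.

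Among the other fixed lists, few members were measured. Of the 6 photosynthesis genes 2 fell in shoots at 12 h, 3 when adjusted over the list alone, with LHCB4.2, a chlorophyll binding protein, at -1.32 ± 0.34. Of 4 auxin response genes 2 fell in shoots at 12 h, 3 when adjusted over the list alone, with IAA29 at -2.24 ± 0.46 and the auxin conjugating gene WES1 at -1.32 ± 0.35. DFR, the dihydroflavonol reductase of anthocyanin synthesis, rose in shoots by 2.17 ± 0.36 at 3 h, and ALDH7B4, an aldehyde dehydrogenase of the osmolyte list, by 2.45 ± 0.19, both also when adjusted over their lists alone. PYK10, a beta-glucosidase abundant in roots and the only one of 3 root markers to rise in shoots at 6 h, had 1.69 ± 0.28, also when adjusted over the list alone. Of the 2 low-oxygen genes of the fixed list, AT4G17260, a lactate dehydrogenase, rose in shoots at 1, 3, 6 and 12 h, with 0.59 ± 0.17, 0.48 ± 0.17, 0.67 ± 0.17 and 0.95 ± 0.17, and fell in roots at 6 h, with -0.71 ± 0.17. Adjusted over the list alone, 1 of the 2 rose in shoots at the same times and in roots at 3 h, and 1 fell in roots at 1, 6 and 24 h. In shoots the calls at 1 h and 3 h ended under several settings, among them quantile normalization (adjusted p = 0.084 and 0.097), and the fall in roots became -0.40 (adjusted p = 0.091) against the mean of 0.25 h and 24 h. AT4G17260 at 1 h was not past the threshold without shoot 0.25 h replicate 1 (adjusted p = 0.24) or shoot 0.25 h replicate 2 (adjusted p = 0.071) or shoot 1 h replicate 1 (adjusted p = 0.32). AT4G17260 at 3 h was not past the threshold without shoot 0.25 h replicate 1 (adjusted p = 0.28) or shoot 0.25 h replicate 2 (adjusted p = 0.0501) or shoot 3 h replicate 1 (adjusted p = 0.19) or shoot 3 h replicate 2 (adjusted p = 0.1). AT4G17260 at 6 h was not past the threshold without shoot 0.25 h replicate 1 (adjusted p = 0.075) or shoot 6 h replicate 1 (adjusted p = 0.082). AT4G17260 at 6 h was not past the threshold without root 0.25 h replicate 2 (adjusted p = 0.1) or root 6 h replicate 1 (adjusted p = 0.11). The only measured starvation gene of the fixed list, AT3G15450, fell in shoots at 12 h, with -2.91 ± 0.75, and of 2 expansins EXPA8 fell, with -1.66 ± 0.53, both also when adjusted over the list alone, though not past the threshold when only the shoot arrays were fitted (adjusted p = 0.051 and 0.071). Neither of the 2 cell cycle genes passed limma's test at any time, over all genes or adjusted over the list alone, with medians between -0.35 and 0.39. Of 4 reference genes, PEX4 was past the test in shoots at 6 h and 12 h, with 0.37 ± 0.13 and 0.41 ± 0.13, and the list's medians lay between -0.10 and 0.11. Of the 36 tested lists and families, 23 had no set test past the threshold in any of the 12 time contrasts. LHCB4.2 at 12 h was not past the threshold without shoot 12 h replicate 2 (adjusted p = 0.052). WES1 at 12 h was not past the threshold without shoot 0.25 h replicate 2 (adjusted p = 0.062) or shoot 12 h replicate 2 (adjusted p = 0.07). AT3G15450 at 12 h was not past the threshold without shoot 0.25 h replicate 2 (adjusted p = 0.06) or shoot 12 h replicate 2 (adjusted p = 0.062). EXPA8 at 12 h was not past the threshold without shoot 0.25 h replicate 1 (adjusted p = 0.14) or shoot 0.25 h replicate 2 (adjusted p = 0.064) or shoot 12 h replicate 1 (adjusted p = 0.099) or shoot 12 h replicate 2 (adjusted p = 0.096). PEX4 at 12 h was not past the threshold without shoot 0.25 h replicate 1 (log2 change 0.26, adjusted p = 0.25) or shoot 12 h replicate 1 (adjusted p = 0.052) or shoot 12 h replicate 2 (adjusted p = 0.13). PEX4 at 6 h was not past the threshold without shoot 0.25 h replicate 1 (log2 change 0.22, adjusted p = 0.31) or shoot 6 h replicate 1 (adjusted p = 0.18). PEX4 was also not past it at 6 h with quantile normalization (adjusted p = 0.061), or at 6 h and 12 h when only the shoot arrays were fitted (adjusted p = 0.091 and 0.075). The most members past the test in the lists and families without such a set test were 8 of 22 serine carboxypeptidase-like genes that rose in shoots at 6 h, 4 of 18 cytochromes P450 and 4 of 13 SWEET transporters that rose at 3 h, 4 of 7 RALF-like peptides and 3 of 7 xyloglucan endotransglucosylases that fell at 6 h. The medians over the 12 contrasts lay between -0.21 and 0.14 for AGAMOUS-like factors, -0.18 and 0.27 for TRICHOME BIREFRINGENCE-LIKE proteins, -0.35 and 0.05 for IQ-domain proteins, -0.41 and -0.03 for TON1 recruiting motif proteins, and -0.36 and 0.39 for tetraspanins. They lay between -0.15 and 0.11 for bZIP factors, -0.10 and 0.21 for ubiquitin-specific proteases, -0.12 and 0.18 for ubiquitin-conjugating enzymes, -0.14 and 0.41 for tau-class glutathione transferases, and -0.29 and 0.70 for alpha-expansins. They lay between -0.44 and 0.36 for Aux/IAA proteins, -0.26 and 0.23 for glutamate receptor-like channels, and -0.23 and 0.56 for cation/H+ exchangers, and the 1 measured response regulator of the added families lay between -1.09 and 0.94 and never passed the test. Median and mean differed in sign in 64 of 564 pairs of list and contrast, none of them past the set test.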

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

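Of the tests reported here, the count over other splits of the arrays and the prediction for an exchanged label were set before their results were seen, and the other tests of an explanation were chosen after. The tests of the tissue difference belong to the design fixed before the data were examined. The counts of probe sets whose change differed between roots and shoots were 385 at 0.5 h, 542 at 1 h, 1978 at 3 h, 3067 at 6 h, 2875 at 12 h and 587 at 24 h, and 5214 in the F test over all times, each by the interaction test. Single genes differed by the same test. AT2G27420 changed by -5.22 in shoots and 0.21 in roots at 6 h, a difference of 5.43. SWEET2 changed by -3.38 and 0.81 at 6 h, a difference of 4.19, and AT5G52390 by -0.78 and 3.34, a difference of 4.12. At 12 h AT5G62280 and AT3G62950 had differences of 4.58 and 4.14. AT4G17470 had a difference of -8.07 at 3 h. AT3G60420, which changed by 3.03 in shoots and -2.93 in roots at 12 h, had -5.96, and AT1G19960 had -5.56. AT1G07050 and AT3G62550 had -5.27 and -5.19 at 6 h. With the larger pseudocount AT5G62280, AT3G62950 and AT3G60420 had differences of 2.55, 2.36 and -3.50.

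Among gene lists, the heat shock genes changed more in roots than in shoots, with median differences of 0.85 at 1 h, 1.31 at 3 h and 0.82 at 6 h (adjusted p = 0.00076, 0.0027 and 0.021, and 0.82, 0.82 and 0.91 with an estimated correlation). The low-oxygen genes differed by -0.96 at 0.5 h, -0.79 at 1 h and -0.60 at 24 h (adjusted p = 0.0064, 0.021 and 0.021, and 0.94, 0.94 and 0.94 with an estimated correlation). The plastid genes differed by 0.27, 0.50, 0.56 and 0.42 at 0.5, 1, 3 and 6 h (adjusted p = 0.00093, 4.0e-13, 1.1e-07 and 0.0025, and 0.94, 0.82, 0.94 and 0.94 with an estimated correlation). The U-box proteins differed by -0.68 at 0.5 h, -0.48 at 1 h and -0.59 at 24 h (adjusted p = 0.00093, 0.001 and 0.033, and 0.52, 0.52 and 0.8 with an estimated correlation). A fit of the 2 tissues alone called 14911 probe sets. Of 100 splits of the 28 arrays into 14 and 14, 1, the real one, gave as many, with at most 0 calls in the others. Each other split mixes the tissues, so a tissue difference widens its spread and lowers its count. The counts therefore show only that the arrays group by tissue, and 100 splits cannot give a share under 1 in 100.

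The 4 shoot arrays of 0.5 h and 1 h match across their labels. The replicate differences of the 2 groups correlate at -0.583, the lowest of 91 pairs of groups, which otherwise lie between -0.227 and 0.197, and this argues against noise that arises separately in each array. An exchange of 1 label between the groups, and a batch or other technical difference that 1 array of each group shares, cannot be told apart here: the difference of the groups' replicate differences correlated with the root change from 0.5 h to 1 h at 0.0454, and the GAPDH 3' to 5' gap was 0.165 against a median of 0.118 and a maximum of 0.46 in the other groups. A correlation under 0.1 had been set beforehand as speaking against an exchange, but after it was seen, single root arrays were found to give -0.061 to 0.144, across that limit, so it decides nothing, and 10 other correlations with root and shoot changes lay between -0.246 and 0.295. Of the matched pairs, replicate 1 of 0.5 h and replicate 2 of 1 h lay nearer to 0.25 h. The SD of their log2 differences from the 0.25 h mean was 0.496 and 0.460, against 0.702 and 0.706 for the other pair. The dehydration genes had mean log2 signals of 6.18 and 6.10 against 7.86 and 8.17. STZ, which was lower by 3 h, had signals of 361 and 291 against 524 and 549. An exchange could give such a gap, and so could a difference that a pair shares. The arrays keep their labels throughout, and differences in the true response of the plants stay open and untested.

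Of the 69 plastid genes 30 rose in roots at 1 h, and the list's median was 0.64, a call that was lost with an estimated correlation. Shoot tissue in the root samples would need 6.86% of the RNA and would raise the nuclear photosynthesis genes by 2.31, but their median was -0.0656 with an SD of 0.28 over members, and 0.65 and -0.72 on the 2 arrays, so it is not the whole source although it could add to replicate 1. The ratio between the values with and without quantile normalization was 1.05. It cannot decide on scaling, since the arrays were already scaled to a common mean and both methods assume an equal total level. RNA quality stays open, since for 1 of 3 housekeeping genes, GAPDH, both arrays of 1 h lie outside both arrays of 0.25 h in the 3' to 5' difference, while for actin and for ubiquitin 1 of the 2 arrays lies below both. The 25S ribosomal RNA signal in roots was also higher at 1 h, 2641 and 2329, than at 0.25 h, 2281 and 2082. The mitochondrial genes rose too, with mean log2 signals of 6.20 and 6.23 against 5.80 and 5.88. A source shared by these RNAs was not tested and stays open. A response of the plastids to drying is a hypothesis that was not tested, because this series has no untreated arrays.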

How the results depend on the processing

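The fits without and with the 4 shoot arrays of 0.5 h and 1 h grouped together were chosen after the results were seen, and the other alternatives beforehand. With an alternative pseudocount, filter, quantile normalization or variance prior, each count of changed probe sets stayed within 1.5 times its value in the report. No named gene change past the threshold changed sign in any alternative. List medians were computed again with quantile normalization, the replicate block, each array left out and without the 4 shoot arrays, and none past the threshold changed sign. They were not compared under another pseudocount, filter, variance prior, array weights, 1 tissue's arrays or the mean reference. The larger side of the up and down counts turned in at least 1 alternative for shoots at 3, 6 and 24 h, roots at 0.5, 1, 3 and 6 h, and the tissue difference at 6 and 24 h. Array weights gave 560 and 647 for shoots at 0.5 and 1 h, 1907, 1875 and 758 for roots at 0.5, 1 and 24 h, and 917 for the tissue difference at 24 h. Fitting only the 14 shoot arrays gave 700, 707 and 1327 at 0.5, 1 and 24 h. Adjustment over all 12 contrasts gave 1332, 1090 and 820 for roots at 0.5, 3 and 24 h, and the mean of 0.25 h and 24 h as reference gave 1717 and 2132 for roots at 0.5 and 1 h. Without the 4 shoot arrays roots gave 1470, 1940, 995 and 653 at 0.5, 1, 3 and 24 h, and the tissue difference at 24 h gave 1066. The 2 groups left out there had the widest spread between replicates, with an SD of 0.608 and 0.588 against at most 0.405 elsewhere. With the 4 as 1 group, 2515 changed. With the estimated correlation 1 of 45 list calls held. Beyond what these constructions show, the cause was not tested.

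Leaving out 1 array moved these counts. Without shoot 0.25 h replicate 1, shoots gave 660, 706 and 948 at 0.5, 1 and 24 h and the tissue difference 340, 1207 and 208 at 1, 3 and 24 h; without replicate 2, shoots gave 637, 647 and 1236 and the difference 203 and 308 at 0.5 and 1 h. Without root 0.25 h replicate 1, roots gave 191, 322, 213, 802, 603 and 211 from 0.5 to 24 h and the difference 213, 261 and 361 at 0.5, 1 and 24 h; without replicate 2, roots gave 535, 815 and 884 at 0.5, 1 and 12 h and the difference 212 and 196 at 0.5 and 24 h. Without shoot 0.5 h replicate 1 or 2, shoots gave 2360 or 599 at that time, and the difference 746 without replicate 1. Without shoot 1 h replicate 1 or 2, shoots gave 362 or 2452 and the difference 359 or 988. Without root 0.5 h replicate 1 or 2, roots gave 377 or 135 and the difference 186 or 137. Without replicate 2 of root 1 h, shoot 3 h, root 3 h, root 6 h, shoot 12 h, root 12 h and shoot 24 h, the counts at that time were 344, 3375, 324, 911, 3185, 561 and 654, and the difference was 313, 1107, 1315, 2004 and 159 for root 1 h, shoot 3 h, root 3 h, root 6 h and shoot 24 h. Without root 24 h replicate 1 or 2, roots gave 224 or 260 and the difference 183 or 296. The full ranges were 599 to 2360, 362 to 2452, 3375 to 3905, 3185 to 3552 and 654 to 1557 for shoots at 0.5, 1, 3, 12 and 24 h, 135 to 535, 322 to 867, 213 to 596, 802 to 1370, 561 to 994 and 211 to 341 for roots, and 137 to 746, 261 to 988, 1107 to 1583, 2004 to 2846 and 159 to 715 for the difference at 0.5, 1, 3, 6 and 24 h.

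The replicate numbers had no effect shared across groups: over 91 pairs of groups the replicate differences correlated at a median of 0.0048, 4 pairs lay over 0.1, and 24 of 28 arrays matched their own replicate best. For shoots and roots of the same time the correlation lay between -0.15 and 0.036. This does not settle whether arrays of 1 time and number came from the same plants. With the replicate number as a block, shoots gave 1354, 1448, 5142, 6023, 4718 and 1893, roots 781, 1189, 644, 1822, 1357 and 382, and root against shoot 15797, each within 1.5 times, with 47 list calls. Of 153 named gene comparisons, 17 lost the call under at least 1 alternative that kept all arrays, 6 more when only that tissue's 14 arrays were fitted, and 34 with 1 array left out. With the larger pseudocount (30th percentile) the log2 value moved by over 1.5 times in 49 of 152 comparisons past the threshold, and 147 of the 152 stayed past it, and with the mean of 0.25 h and 24 h as reference in 29 of 115, and 105 of the 115 stayed past it. Only the change of STZ in shoots at 0.5 h, not past the threshold, changed sign, with 0.36 without shoot 0.5 h replicate 1 and -0.17 without replicate 2. The dehydration list was lost at 0.5 h without shoot 0.5 h replicate 2 (adjusted p = 0.081) and at 1 h without shoot 1 h replicate 1 (0.058), and the UDP-glycosyltransferase list at 12 h in 11 fits with 1 array left out (from 0.05 to 0.075).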

Other observations

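The tests of time of day and of scaling given here were chosen after the result was seen. A set of 197 probe sets was past the test and lower at 3 h in both tissues, STZ and WRKY53 among them. Its median in shoots was 0.00 at 0.5 h, -0.08 at 1 h, -1.19 at 3 h, -1.18 at 6 h, -0.79 at 12 h and -0.62 at 24 h, and in roots -0.20, -0.59, -1.22, -1.34, -1.27 and -1.08. Time of day could give such a set, but it would return by 24 h, near the clock time of the reference. In 151 probe sets picked on replicate 1 and measured on replicate 2, the median was -1.74 at 3 h and -1.19 at 24 h in shoots, a ratio of 0.683, and -1.43 and -1.71 in roots, a ratio of 1.19, so time of day alone is argued against. Within a tissue both changes share 1 array of 0.25 h, so a deviation of that array moves the ratio toward 1. The replicates may also be technical, so the set and its measurement may not be independent. The ratio between the set's median at 3 h with and without quantile normalization was 0.957 in shoots and 1.08 in roots. The arrays were already scaled to a common mean, and array medians differed by at most 1.10 times within a tissue. Both methods assume an equal total level, so this ratio cannot decide on scaling of the arrays. An early response to drying or handling that had faded by 3 h remains a hypothesis, which needs untreated arrays to test.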
